A study of Homo sapiens with 2 samples.

How the data were processed

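The series holds 2 samples of HT-29 cells, exposed to spores or to vegetative cells of Bacillus subtilis, each hybridised against unchallenged HT-29 cells on 4 two-colour arrays. Per the series' design text, dye-swapped hybridisations of each sample were 4 biological replicates, so each array counted as 1 replicate. No source says whether a pair of swapped arrays shares RNA extracts, and averaging arrays of opposite dye on a slide was tried as an alternative. The deposited scanner files hold spot and local background intensity values on a linear scale in 2 channels, Cy5 and Cy3, without normalization, per the file headers (QuantArray). A deposited table of values gives a single value per row and sample, on a log2 scale judged from its values, which the authors made with limma in R 2.13.0 per the submitters' processing notes. Its centring was near 0 (column medians -0.000775 for spores and -0.00381 for vegetative cells), and its rows carry no gene names. Its direction is stated only by the sample titles, which name spores or vegetative cells against control.

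The dyes of each array were taken from the names given to the deposited arrays, with challenged RNA in Cy3 on spore arrays 1 and 3 and vegetative arrays 2 and 4, and in Cy5 on the others. Ratios were turned to challenged over unchallenged cells. The table of values has 1352 rows, as many as the arrays have names. Matched in alphabetical order it correlated with the fit at 0.952 for vegetative cells and at -0.866 for spores, with slopes of 0.706 and -0.487, while 1000 shuffled orders gave at most 0.110 and 0.102 in size. The vegetative column thus follows its title as the arrays' dyes give it and the spore column runs against them. Either the dyes named for the spore arrays or the sign of that column is at odds with the title, so the direction of the spore values stays unknown, and no single gene was read from the table.

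Each array had 3168 spots in 6 blocks, 2754 of them with gene names, 228 marked N/A and 186 empty. Background was corrected with normexp (offset 50), and arrays were normalized by loess with unnamed, empty and ignored spots at weight 0. The 9 to 24 spots per array marked to be ignored were left out. Spots of 1 name were averaged as log2 ratios. Local background medians were 5.63 to 60.4 in Cy5 and 1.05 to 21.1 in Cy3, and the planned filter (foreground 2 background SDs above local background in a channel on at least 4 arrays) removed 0 names, so it was void. Of 1352 array names, 1240 matched a symbol and 85 a synonym in the RefSeq table of assembly GRCh38.p14, used only for symbols, and 27 kept the array's name. Names with the same symbol were represented by the brighter one, which left 1351 genes. No probe identifiers, sequences or coordinates are in the files.

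The fit used limma 3.58.1 in R 4.3.3 with the data.table package (version 1.17.8). One model over all 8 arrays had a term for spores, a term for vegetative cells and a dye intercept (residual df 5, prior df 4.16), with eBayes and Benjamini-Hochberg adjustment over genes at 0.05. The difference was the contrast spores minus vegetative. Of 26 gene lists fixed beforehand, 24 with at least 5 measured members were tested with camera (preset correlation 0.01, and estimated) and fry on the 1338 genes without missing values, with Benjamini-Hochberg adjustment over lists. The remaining 2 lists had 2 and 4 measured members. The correlation and overlap of both comparisons were set against 100 simulations and against independent lists. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

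The design, the lists, the named genes and most alternatives were set before the data were examined. Named genes are, per comparison with unchallenged cells, up to 12 rises and 12 falls past the threshold with the same sign on all 4 arrays, examples from the lists (2 to 4 per list, by size), and 20 fixed genes whatever their values, of which NOD2 is not on the array. For the difference they are the 6 largest on each side. Other genes are said to be chosen after their values were seen.

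The procedure was tested on simulated data with known changes in the real arrays' spread over 1351 genes. For spores it recovered 55.2% of log2 changes of 0.5, 95.5% of changes of 1 and 100% of changes of 2, with 2.34% false calls. For vegetative cells these were 52.2%, 100% and 100%, with 7.69% false, and for the difference 17.9%, 85.1% and 100%, with 3.57% false. A list of 20 genes shifted by 0.5 was called by camera with either correlation and by fry, and 0 of 19 unshifted lists were. The simulated genes were independent of each other, so false list calls where members move together were not tested. In the data the immediate early genes had an estimated correlation of 0.169, against the preset of 0.01.

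Alternatives covered background correction, normalization within and between arrays, filters, ignored spots, the dye term, slide and array number as random blocks, the replicate unit, the samples in the fit, the variance prior, thresholds and leaving out each array. Left out of the gene tests were the unnamed and empty spots, which were looked at apart for signal and for change. The files hold no scan settings that would let slide and culture be separated.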

Results

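HT-29, an established line of human colonic adenocarcinoma cells often used as a model of the gut epithelium, was exposed for 3 h to spores or to vegetative (actively growing) cells of the probiotic bacterium Bacillus subtilis, strain R0179, at 100 bacteria per cell. RNA of each exposed culture was hybridised against RNA of unchallenged HT-29 cells on two-colour arrays that carry mainly immune genes. The 2 samples, spores and vegetative cells, had 4 arrays each, with the dyes swapped on 2 arrays of each sample, so that 8 arrays on 5 slides were compared. The median intensity of the spots with gene names ranged from 452 to 1688 in Cy5 and from 544 to 1606 in Cy3. The empty spots had medians of 339 to 1347 in Cy5 and 395 to 1152 in Cy3, close to those of the named spots, so the folds of weakly expressed genes were compressed. Of the 1351 genes tested, 597 lay above 1.5 times the median empty spot in at least 1 channel on at least 4 arrays. Fold changes below are challenged over unchallenged cells, each with the standard error of the fit and n = 4 arrays per group, and the number of arrays limits their precision.

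Vegetative cells against unchallenged cells addressed how growing bacteria alter epithelial immune genes. Chemokines that attract neutrophils rose: CXCL8 (interleukin 8) rose 10.04-fold (log2 3.33 ± 0.19, adjusted p = 1.3e-05), CXCL3 9.87-fold (3.30 ± 0.21), CXCL1 8.02-fold (3.00 ± 0.33) and CXCL2 7.53-fold (2.91 ± 0.20). CCL20, which draws dendritic cells and lymphocytes to mucosa, rose 9.88-fold (3.30 ± 0.22), and CX3CL1, a chemokine anchored on epithelial membranes, rose 7.82-fold (2.97 ± 0.21). Among cytokines, IL17C, an epithelial cytokine of antibacterial defence, rose 8.23-fold (3.04 ± 0.38, adjusted p = 0.0011), TNF 6.78-fold (2.76 ± 0.47, adjusted p = 0.0066) and CSF2, a growth factor for granulocytes and macrophages, 6.41-fold (2.68 ± 0.23). Regulators of NF-kB rose with them, TNFAIP3 (A20) 7.33-fold (2.87 ± 0.24), BCL3 3.87-fold (1.95 ± 0.12) and NFKBIA (IkB alpha) by a log2 of 1.57 ± 0.15, with 0.88 on vegetative array 4 against 1.72 to 1.87 on the others and saturated spots on 2 of the 4 arrays. The transcription factor IRF1 rose 4.72-fold (2.24 ± 0.11, adjusted p = 1.1e-05), and PTGS2, the inducible cyclooxygenase, rose by a log2 of 1.02 ± 0.11. Each of these genes was higher on all 4 vegetative arrays. IL17C, CX3CL1, TNF and CSF2 lay above the empty spots in the unchallenged channel on 0 of the 4 arrays, and CXCL8 and CCL20 on 2, so their folds understate the change. TNF had a mean log2 ratio of 4.09 on 1 slide and 1.43 on the other.

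Lower with vegetative cells were the growth regulators TGFB2 (log2 -0.96 ± 0.15, adjusted p = 0.0039; -0.51 on vegetative array 2 and -1.15 to -1.05 on the others) and CDKN2B, a cell cycle inhibitor (-0.82 ± 0.16). MAP3K14, the kinase of the alternative NF-kB pathway, fell (-0.78 ± 0.15), as did the secreted factor FAM3C (-0.71 ± 0.12), the Ras exchange factor SOS2 (-0.67 ± 0.15), the interleukin 1 decoy receptor IL1R2 (-0.64 ± 0.10), the interferon-induced gene IFIT1 (-0.64 ± 0.10), the complement inhibitor CD55 (-0.57 ± 0.12) and the phosphatase DUSP14 (-0.56 ± 0.11). SNAI1 (-0.70), ITGAM (-0.60) and CCL1 (-0.54) also passed the threshold downwards, with signals near those of the empty spots. TJP1 (ZO-1), which joins tight junctions to the cytoskeleton, fell by 0.51 ± 0.12 on the log2 scale (adjusted p = 0.039), but it was lower on only 3 of the 4 arrays, with -1.14 and -0.90 with vegetative cells in Cy5 and -0.08 and 0.10 in Cy3. IL1B rose weakly (0.56 ± 0.14, adjusted p = 0.039). The fixed genes IL6 (-0.10), IL10 (-0.41), TLR2 (-0.11), TLR4 (-0.11), TLR5 (-0.25), MYD88 (0.21), JUN (0.06) and EGR1 (0.50, adjusted p = 0.19) did not pass the threshold, and single arrays lay apart for IL10 and JUN. In all, limma with Benjamini-Hochberg adjustment called 95 of the 1351 genes, 74 higher and 21 lower, and 90 of them had the same sign on all 4 arrays. At an unadjusted p under 0.05 there were 237 genes, against 67.6 expected by chance. The count fell to 54, 58, 48 and 51 without vegetative arrays 1, 2, 3 and 4, and it was 78 to 97 without any one spore array. With arrays on one slide averaged to 1 replicate, 32 genes were called, all higher and 0 lower (189 at an unadjusted p under 0.05), so TGFB2, MAP3K14, IL1R2, TJP1 and every other fall lost its call.

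By gene list, camera asked whether a list shifted against the other genes, and fry whether its members moved on balance, without reference to other genes; with an estimated correlation camera called 0 lists. Of 39 chemokines, 7 were higher and 1 lower (adjusted over the list alone, 8 and 2), and camera set the list above the other genes (adjusted p = 0.025; adjusted p = 0.55 with an estimated correlation). The chemokine list missed the camera threshold with median centring (0.11) and without vegetative array 2 (0.0504). Fry gave an adjusted p of 0.0036 for chemokines. Of 26 NF-kB subunits and regulators, 6 were higher, among them NFKBIE (log2 1.05), and 1 was lower (adjusted over the list alone, 7 and 1; camera adjusted p = 0.040; adjusted p = 0.55 with an estimated correlation; fry 0.0036). The NF-kB call was lost without spore arrays 3 (0.056) and 7 (0.060) and without vegetative arrays 1 (0.089), 2 (0.0504) and 3 (0.081). Of 15 immediate early genes, which answer a signal within minutes, 6 were higher (adjusted over the list alone, 8), led by NR4A1 (1.28), FOS (1.14 ± 0.17), JUNB (1.01) and DUSP1 (0.94 ± 0.12), with camera adjusted p = 0.024, adjusted p = 0.67 with an estimated correlation and fry 0.023, and camera gave 0.066 without vegetative array 1. Of 24 pro-inflammatory cytokines, 7 were higher (adjusted over the list alone, 7), including LIF (1.83), with camera adjusted p = 0.077, adjusted p = 0.67 with an estimated correlation and fry 0.015. Growth factors had 3 of 18 members higher (adjusted over the list alone, 4 higher and 1 lower), with VEGFA (0.75) and PDGFA (0.52) in front. The Toll-like receptor pathway had 2 of 26 higher, the adaptor TICAM1 (1.15) and the kinase IRAK2 (0.60), and the interleukin receptors had IL22RA1 (0.71) and IL15RA (0.70) higher and IL1R2 lower among 27. The interferon and JAK-STAT list had 3 of 46 higher, such as IRF1 and STAT5A (0.99), and 1 lower, with a mean above 0 and a median and camera direction below 0. Of 22 anti-inflammatory and regulatory mediators, SOCS3 was higher (1.41) and TGFB2 and IL1R2 were lower (adjusted over the list alone, 2 and 4). Tight junction genes split, with CLDN3 higher (0.45) and TJP1 and CLDN1 (-0.46) lower among 13, and adhesion molecules split between SELPLG (0.64) and the lower ITGAM and CD58 (-0.49) among 18. Single members were called in the lists of MAP kinases (MAP3K8, 1.27, of 36), heat shock genes (HSPB1, 0.69, of 16), the TNF receptor superfamily (TNFRSF14, 0.57, of 26), complement (CD55, of 7) and leukocyte markers (ITGAM, of 31, with 0 members above the empty spots). Antigen presentation, antimicrobial peptides, apoptosis regulators, chemokine receptors, housekeeping genes, the NOD and inflammasome list, stromal markers and T helper cytokines had 0 members past the limma threshold, with 7 of their 105 genes at an unadjusted p under 0.05. Of the 24 lists, camera called 3, camera with an estimated correlation 0 and fry 4, and camera called only the immediate early genes without vegetative array 2.

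**Figure D1:**
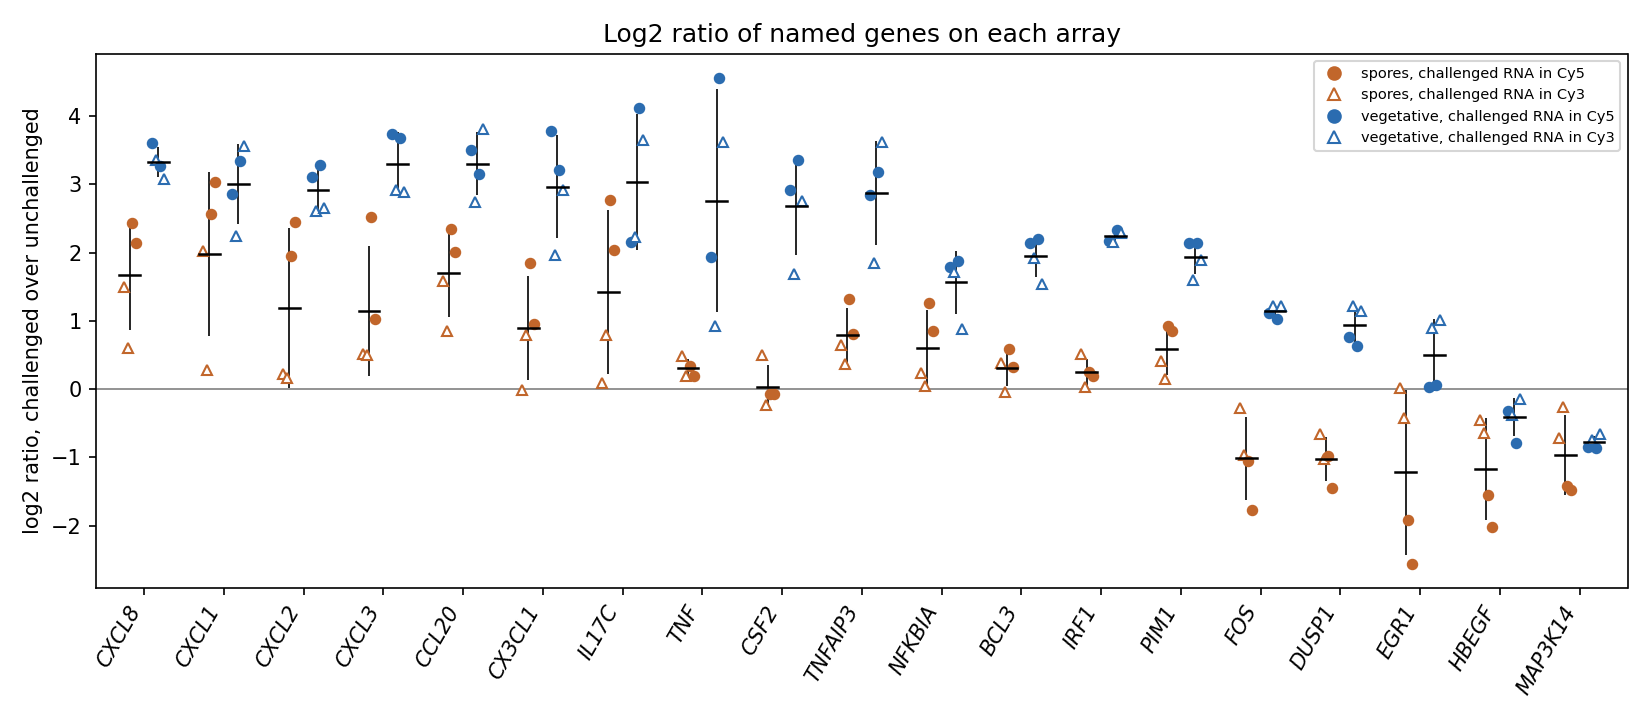
Log2 ratio of challenged over unchallenged HT-29 cells per array for 19 named genes, with spores in orange and vegetative cells in blue; circles are arrays with challenged RNA in Cy5, triangles those with it in Cy3, and black bars with lines give the mean ± SD (n = 4 arrays). CXCL8 averaged a log2 of 3.33 with vegetative cells and 1.67 with spores, read as the dyes are named, and the authors' table gives the spore values the opposite sign.

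Spores against unchallenged cells asked the same of the dormant form, and the sign of every spore value below is contested. The dyes named for the spore arrays give the direction used here, but the authors' own value table has the opposite sign for spores: matched in alphabetical order, it correlated with the fitted log2 fold changes at r = -0.87 across genes for spores and at 0.95 for vegetative cells. Read as the dyes are named, CXCL1 was 3.93-fold higher (log2 1.98 ± 0.33, adjusted p = 0.029), CCL20 3.25-fold (1.70 ± 0.22, adjusted p = 0.010), CXCL8 3.18-fold (1.67 ± 0.19, adjusted p = 0.0081), CXCL2 2.29-fold (1.19 ± 0.20) and CXCL3 2.21-fold (1.14 ± 0.21). The survival kinase PIM1 (0.58 ± 0.11) and JAK3 (0.54 ± 0.10) were also higher. The transcription factors EGR1 (-1.22 ± 0.19, adjusted p = 0.019) and FOS (-1.01 ± 0.17), and DUSP1, the phosphatase that shuts off MAP kinases (-1.02 ± 0.12, adjusted p = 0.0081), were lower, each an early gene of growth and stress signals. HBEGF, a ligand of the EGF receptor (-1.16 ± 0.17), MAP3K14 (-0.96 ± 0.15), the interleukin 12 subunit IL12A (-0.86 ± 0.12), the antigen-presenting HLA-DRA (-0.66 ± 0.13) and the stress factor DDIT3 (-0.61 ± 0.11) were lower too. With the sign turned, the chemokines CXCL1, CCL20 and CXCL8 would be lower by the same sizes and EGR1, FOS, DUSP1 and HBEGF higher. The called chemokines and the called immediate early genes lay on opposite sides of 0, with medians of 1.67 and -1.02 as the dyes are named, and turning the sign swaps the sides. JAK3, IL12A and HLA-DRA had signals near those of the empty spots.

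With spores TNF (0.30, adjusted p = 0.88), IL1B (0.09), IL6 (0.38), IL10 (0.13), NFKBIA (0.60, adjusted p = 0.14), TNFAIP3 (0.79, adjusted p = 0.24), TLR2 (-0.27), TLR4 (0.26), TLR5 (0.03), MYD88 (0.04, with 0.30 on spore array 4), JUN (-0.39), PTGS2 (0.27) and TJP1 (0.00) did not pass the threshold. limma called 15 of the 1351 genes, 7 higher and 8 lower, and 137 had an unadjusted p under 0.05, against 67.6 expected. With the spore arrays alone limma called 0 genes (105 at an unadjusted p under 0.05), and with no dye intercept it called 3. All 15 but EGR1 had the same sign on all 4 spore arrays, and EGR1 had log2 ratios of 0.01, -0.42, -1.91 and -2.55. Each of the 15 was larger with spores in Cy5 (arrays 4 and 7, median size 1.58) than with spores in Cy3 (arrays 1 and 3, 0.485). Of the 95 vegetative calls, 70 were larger with challenged RNA in Cy5, with median sizes of 0.896 in Cy5 and 0.735 in Cy3. Across genes the spore arrays correlated at -0.14 to 0.29, against 0.32 to 0.68 among the vegetative arrays. Spore arrays of the same dye orientation correlated at 0.23 (1 and 3) and 0.29 (4 and 7). Those of opposite orientation correlated at -0.14 to 0.0013, so across genes the spore ratios did not agree between the dye orientations. The spore calls depended on single arrays: 6, 5, 2 and 3 genes were called without spore arrays 1, 3, 4 and 7, and 9, 7 and 9 without vegetative arrays 1, 3 and 4, which share the estimate of the spread. DUSP1 was called in each of these fits.

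Among the lists, the immediate early genes were lower with spores, with EGR1, DUSP1 and FOS called among 15 (adjusted over the list alone, 6 lower; camera adjusted p = 8.4e-07; adjusted p = 0.35 with an estimated correlation; fry 0.066). Chemokines were higher, with CXCL1, CCL20, CXCL8, CXCL2 and CXCL3 called among 39 (adjusted over the list alone, 6 higher; camera adjusted p = 0.044; adjusted p = 0.35 with an estimated correlation; fry 0.085). The chemokine list lost its call without background correction (0.086) and without spore arrays 1 (0.26), 4 (0.061) and 7 (0.13). Both directions turn with the spore sign. The other calls were single members of their lists, namely HLA-DRA of 23 antigen presentation genes, HBEGF of 18 growth factors, DDIT3 of 16 heat shock and stress genes (adjusted over the list alone, 1 higher and 4 lower), JAK3 of 46 interferon and JAK-STAT genes, MAP3K14 of 26 NF-kB genes and IL12A of 24 pro-inflammatory cytokines. Of the 24 lists, camera called 2, camera with an estimated correlation 0, and fry 0 for a shift on balance and 9 for change in either direction. Without spore array 1, 4 or 7, camera called only the immediate early genes.

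Spores against vegetative cells asked whether the bacterial forms differ in what they do to the epithelial cells. As the dyes are named, CSF2 was lower with spores by a log2 difference of -2.64 (adjusted p = 0.0025), CXCL3 by -2.16 (0.0035), FOS by -2.16 (0.0017), TNFAIP3 by -2.09 (0.012), CX3CL1 by -2.07 (0.0059) and IRF1 by -1.99 (0.00061). DUSP1 (-1.97), EGR1 (-1.72), CXCL2 (-1.72), CXCL8 (-1.66), BCL3 (-1.64), CCL20 (-1.60), PIM1 (-1.36) and PTGS2 (-0.75) were lower as well. TNF (-2.46, adjusted p = 0.12), IL17C (-1.62, adjusted p = 0.21) and CXCL1 (-1.03, adjusted p = 0.41) did not pass the threshold as the dyes are named. In unchallenged cells CSF2, CX3CL1, TNF and IL17C lay near the empty spots on the vegetative arrays, so the sizes of their differences are uncertain. limma called 33 genes, all lower with spores, and 173 had an unadjusted p under 0.05, while 5 genes were higher without background correction, 6 with plain subtraction and 10 among the genes above the empty spots. The 3 spore slides and 2 vegetative slides held arrays of 1 sample each. With arrays on one slide averaged to 1 replicate, 19 of the 33 genes were called. A fit with the slide as a random block called 36 genes, but that block was fitted to Cy5 over Cy3 ratios. RNA shared by swapped arrays would correlate negatively there, so the block does not test the slide as the replicate. Without vegetative array 4 the count was 21. With the spore sign turned 77 genes were called, 23 higher and 54 lower with spores, and 23 of the 33 were among them. FOS (-0.13, adjusted p = 0.83), DUSP1 (0.08, adjusted p = 0.86) and EGR1 (0.72, adjusted p = 0.19) then lost their calls, while CXCL8 (-5.00) and CCL20 (-5.01) differed more. TNF (-3.07, adjusted p = 0.027), IL17C (-4.46, adjusted p = 0.0012) and CXCL1 (-4.98, adjusted p = 0.00024) then passed the threshold. As the dyes are named, immediate early genes were lower with spores as a list, with 5 of 15 called (adjusted over the list alone, 9; camera adjusted p = 4.2e-08; adjusted p = 0.40 with an estimated correlation; fry 0.015), and so were NF-kB genes, with 3 of 26 (adjusted over the list alone, 4; camera 0.037; adjusted p = 0.46 with an estimated correlation; fry 0.017). With the spore sign turned neither list was called, with a mean of 0.03 (camera adjusted p = 0.88) for the immediate early genes and camera adjusted p = 0.11 for the NF-kB genes, and the chemokines were lower with spores (camera adjusted p = 0.033; adjusted p = 0.68 with an estimated correlation). As the dyes are named, chemokines had 5 of 39 lower (adjusted over the list alone, 2 higher and 6 lower; camera adjusted p = 0.20). Camera called 2 lists, and the NF-kB call was lost without spore arrays 3 (0.064), 4 (0.15) and 7 (0.11) and without vegetative arrays 1 (0.072) and 3 (0.095).

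Genes called with both forms numbered 9. CXCL1, CXCL2, CXCL3, CXCL8, CCL20 and PIM1 were higher with both, against 0.383 genes expected from independent lists, and MAP3K14 was lower with both, against 0.124. FOS and DUSP1 were lower with spores and higher with vegetative cells, against 0.438. With the spore sign turned these become 2 genes higher with both (FOS and DUSP1), 6 lower with spores and higher with vegetative cells, and MAP3K14 higher with spores and lower with vegetative cells. Both comparisons share one estimate of the spread per gene, and 12 of 15 spore calls and 83 of 95 vegetative calls lay above the empty spots. The lists are therefore not strictly independent, and the expected counts can be too low. The overlap was 3, 5, 1 and 3 genes without spore arrays 1, 3, 4 and 7, 4 without vegetative array 3 and 5 without vegetative array 4, and 6 without vegetative array 1 or 2. Across all 1351 genes, which are not independent replicates, the log2 fold changes of the forms correlated at r = 0.358 (Spearman rho 0.166, covariance 0.0358). In 100 simulations without effects the mean r was -0.00149 (-0.0557 to 0.0510) and the mean covariance -4.7e-05. The simulated genes were independent of each other and the simulated arrays shared no controls, so this range can be too narrow. With the spore sign turned r was -0.358. Over the 597 genes above the empty spots r was 0.50 (rho 0.281). No source states whether both forms were set against the same control cultures.

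**Figure D2:**
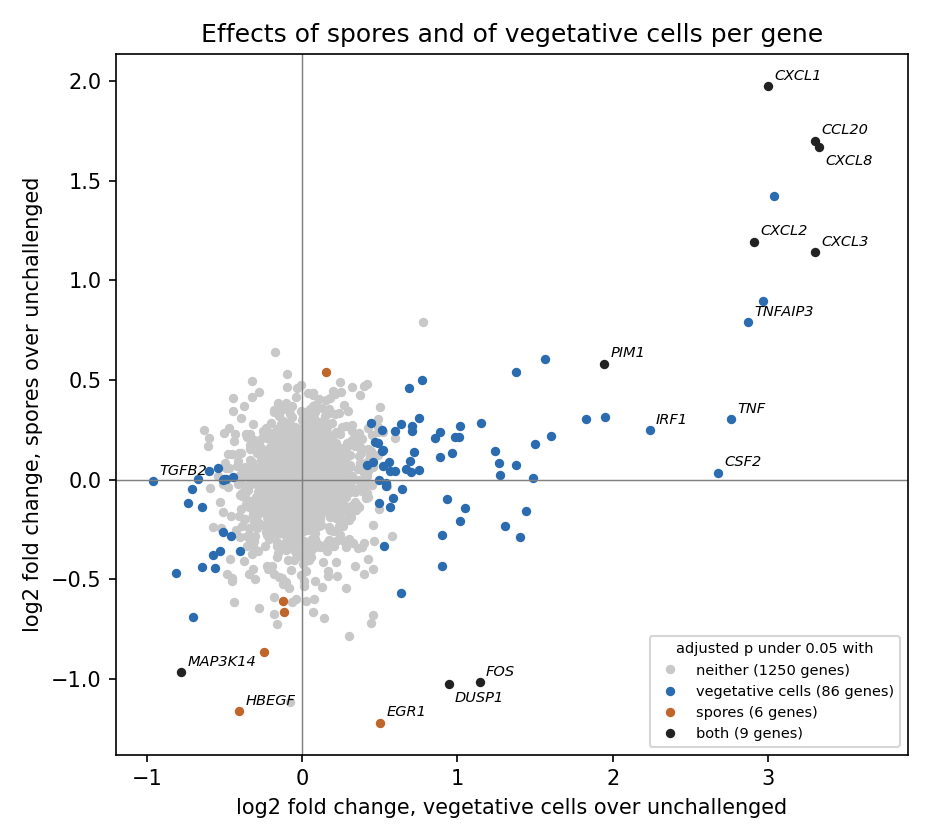
Log2 fold change over unchallenged cells with vegetative cells (x axis) and with spores (y axis, as the dyes are named) for 1351 genes, coloured by the comparison in which limma called them. The 9 genes called in both include CXCL8 at 3.33 and 1.67 and FOS at 1.14 and -1.01, and turning the spore sign would mirror the y axis.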

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

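The tests of the spore sign, of the chemokines and immediate early genes with spores, and of dye bias for TNF were chosen after the results were seen. The splits and sign changes for chance were set before. The empty-spot and slide tests of TNF were written before they were run, but for a gap already seen.

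The spore values have the opposite sign in the authors' table. Another row order in the table is argued against, since 18 of the 20 table entries highest with vegetative cells lay below 0 with spores, whereas 18 of the 20 highest genes lay above 0 on the scanner arrays. Wrongly recorded dyes on 1 spore array are argued against too, because the 7 chemokines higher with vegetative cells had a median above 0 on each spore array, 0.50 at the lowest and 2.35 at the highest. Wrongly recorded dyes on all 4 spore arrays and a turned sign in the table cannot be told apart, because either gives the correlation of -0.87. Whether spores raised CXCL8 and lowered FOS, or the reverse, therefore stays open.

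With spores CXCL1, CCL20, CXCL8, CXCL2 and CXCL3 lay on the other side of 0 from EGR1, DUSP1 and FOS, whereas with vegetative cells FOS, DUSP1 and the chemokines were all higher. Gene-specific dye bias is argued against as the whole source, since the 15 immediate early genes had a median of -0.14 with spores in Cy3 and -0.40 with spores in Cy5, although 5 of them had opposite signs and EGR1 was 0.01 on 1 array. Across all genes, however, spore arrays of opposite dye orientation correlated at only -0.14 to 0.0013. A dye component in the sizes therefore stays open. Loess as the source is argued against by median centring alone, which left the list lower (camera adjusted p = 1.9e-08). Median centring leaves any intensity-dependent trend in the ratios, and all 15 members lay above the empty spots, so it cannot exclude such a trend. Turning the spore sign mirrors both groups of genes and so tests nothing here. These 8 genes kept their sign on all 4 spore arrays over 3 slides, except EGR1 on 1 array. They were called on these same arrays, so their shared sign is no separate support. A response of epithelial cells to spores that may part both groups stays open. The list did not pass with an estimated correlation (adjusted p = 0.35), so this remains a hypothesis.

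TNF was higher on the slide of vegetative arrays 3 and 4 (mean log2 ratio 4.09) than on that of arrays 1 and 2 (1.43), a gap of 2.66 ± 0.34 that did not pass the threshold (limma adjusted p = 0.061). Between these slides limma called 0 of 1351 genes, with 38 at an unadjusted p under 0.05. Dye bias is argued against by gaps of 2.62 and 2.70 in the dye orientations. Brighter empty spots in the channel of unchallenged cells are argued against by their log2 ratio there of at most 0.87, below the lower 95% bound of the gap, 1.88. That bound is for TNF alone and is not adjusted over the 1351 genes, so it can be too high. The slide or its scan and separate cultures with unlike TNF responses cannot be told apart from the gap of 2.66, since each slide holds 2 arrays of its own, and no biological explanation was tested. Gaps between the slides were smaller for IRF1 (0.14), BCL3 (-0.16), CX3CL1 (0.19), CXCL8 (-0.31), CCL20 (0.35) and CSF2 (0.76). IL17C had 1.70 (limma adjusted p = 0.999). The gaps differed in sign between the dye orientations for CX3CL1 (-0.57 in Cy5 and 0.95 in Cy3), CCL20 (-0.36 and 1.06) and BCL3 (0.06 and -0.38).

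Single arrays lay far from the other 3 of their sample for 5 genes. MYD88 had a log2 ratio of 0.30 on spore array 4, against -0.07 to -0.01. IL10 had -1.36 on vegetative array 1, against -0.22 to 0.01, and TGFB2 -0.51 on vegetative array 2, against -1.15 to -1.05. On vegetative array 4, JUN had -0.42, against 0.17 to 0.25, and NFKBIA 0.88, against 1.72 to 1.87. Chance alone gives about 3.8 such arrays in the 76 sets of 4 tested.

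The tested difference between spores and vegetative cells called 33 genes and rests on the contested spore sign. As the dyes are named the log2 differences were -2.64 for CSF2, -2.16 for CXCL3, -2.16 for FOS, -2.09 for TNFAIP3, -2.07 for CX3CL1, -1.99 for IRF1, -1.97 for DUSP1, -1.72 for EGR1, -1.72 for CXCL2, -1.66 for CXCL8, -1.64 for BCL3, -1.60 for CCL20, -1.36 for PIM1 and -0.75 for PTGS2. With the sign turned 77 genes were called, 23 of them higher with spores, and FOS (-0.13), DUSP1 (0.08) and EGR1 (0.72) were not called, while CSF2 (-2.72), CXCL3 (-4.45), TNFAIP3 (-3.66), CX3CL1 (-3.87), IRF1 (-2.49), CXCL2 (-4.11), CXCL8 (-5.00), BCL3 (-2.26), CCL20 (-5.01), PIM1 (-2.53) and PTGS2 (-1.29) were lower with spores in both readings. Of the 34 splits of the 8 arrays into 4 and 4 that could be fitted, 1 (the real one) gave as many genes and the highest of the others gave 0. This argues against chance for this count as the dyes are named, provided that the 8 arrays are independent replicates, as the design text has it. A share of 1 in 34 is the smallest that these splits can give, and the turned spore sign was not split. With the 5 slides as units there are 10 splits, too few for a share under 0.05, and 19 genes were called with arrays on one slide averaged. For its 2 gene lists, 5 of the 34 splits gave as many, with 2 in the highest of the others, so chance is not excluded. The 8 sign changes of the 4 arrays of a sample are too few for a share under 0.05. For spores the real signs gave 15 genes and 2 lists, and the others at most 0 genes and 1 list, so 1 of the 8 gave as many of either. For vegetative cells the real signs gave 95 genes and 3 lists, and the others at most 0 genes and 1 list, again 1 of the 8.

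Spots without a gene name carried signal: 3 of 93 pairs of empty spots and 4 of 114 pairs of N/A spots were above 5 times the median empty spot in both channels on all 8 arrays. Of all these pairs limma called 0 with spores or vegetative cells (at an unadjusted p under 0.05, 4 and 7 empty and 8 and 10 N/A pairs), and the highest log2 fold changes with vegetative cells were 0.79 for empty and 0.77 for N/A spots.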

How the results depend on the processing

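The filter to genes above the empty spots, the turned spore sign (for genes and lists), the array-number block and a dye intercept per sample were chosen after seeing the data. All 15 named genes called with spores, 29 with vegetative cells and 6 for the difference kept their direction in 12 settings, but only DUSP1, 17 and 5 of them kept their call in each. Most genes named against unchallenged cells were chosen for the same sign on all 4 arrays, and 8 of the settings leave out 1 array. Their kept direction was therefore largely given in advance. The counts were 15 genes for spores, 95 for vegetative cells and 33 for the difference. They were 35, 153 and 69 without background correction, 33, 155 and 71 with plain subtraction, 8, 32 and 19 with arrays on one slide averaged (fewer replicates; all 32 vegetative calls higher and 0 lower, 189 unadjusted), and 36, 148 and 76 among genes above the empty spots (fewer genes tested). For spores they were 9 with normexp offset 10, 9 with median centring, 3 with no dye intercept, 25 at adjusted p under 0.1, and 0 with the spore arrays alone (limma, 105 at an unadjusted p under 0.05). With the vegetative arrays alone 58 genes were called, and with the spore sign turned 77 differed. Leaving out 1 array gave 2 to 11, 48 to 97 and 21 to 36. The spore calls, 7 higher and 8 lower, split into 9 and 26 without background correction, 8 and 25 with plain subtraction, 11 and 25 among genes above the empty spots and 5 and 11 with scale normalization. In the first 3 of these settings 5, 6 and 10 genes were higher with spores in the difference. Median centring split the vegetative calls into 71 and 7, against 74 and 21.

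Camera with an estimated correlation called 0 lists for spores, 0 for vegetative cells and 0 for the difference, against 2, 3 and 2 (fry 0, 4 and 2), and leaving out 1 array gave 1 to 2, 1 to 3 and 1 to 2. With the spore sign turned the spore lists changed direction by construction (chemokines, adjusted p = 0.044; immediate early genes, 8.4e-07), and the difference called 1 list, the chemokines, lower with spores (0.033), while the immediate early genes lost their call (0.88). The overlap of 9 genes was 24 without background correction, 3 with no dye intercept and 1 to 6 without 1 array. The correlation of 0.36 became -0.36 with the spore sign turned, by construction, and was 0.26 to 0.38 without 1 array. Except where a reason is given, the cause was not tested. Same-numbered arrays of the samples deviated with correlations of -0.17, -0.23 and -0.20. Each such pair held challenged RNA in opposite dyes, so gene-specific dye bias alone would make these values negative. They cannot show whether the array number pairs the samples. With the number as a replicate block and a dye term (consensus correlation 0.0993), 15, 98 and 36 genes were called. With the slide as a block (consensus correlation 0.0418) 15, 101 and 36 genes were called. The slide block was fitted to Cy5 over Cy3 ratios, so it does not test whether swapped arrays share RNA. With trend and robust eBayes 10, 95 and 31 genes were called, and with a dye intercept per sample 11, 89 and 29. The authors' table names no genes and gives no test, so it was not run as a source of values, and the stricter background filter removed no gene. The signal over the empty spots limits weakly expressed genes, since only 597 of 1351 lay above 1.5 times their median.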

Other observations

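The genes named below lie outside the fixed lists, except VEGFA and KDR. These genes and the test of low oxygen were chosen after their values were seen. With vegetative cells FGF19, a gut hormone, rose by a log2 of 1.60 ± 0.20, the epithelial transcription factor ELF3 by 1.49 ± 0.12 and BMP2 by 1.44 ± 0.15, together with ID1 (0.93 ± 0.12) and SMAD7 (0.90 ± 0.13), which answer BMP and TGF-beta signals. FGF19, ELF3, BMP2, ID1 and SMAD7 also differed from spores as the dyes are named, by -1.38, -1.48, -1.60, -1.03 and -1.34, and with the spore sign turned by -1.82, -1.50, -1.28, -0.83 and -0.47, where SMAD7 was not called (adjusted p = 0.21).

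NDRG1 (2.83-fold), ADM (log2 1.30 ± 0.15) and VEGFA (log2 0.75 ± 0.12), genes known to rise at low oxygen, were higher with vegetative cells, which could point to oxygen used up by growing bacteria. Of 49 other genes known to rise at low oxygen, 10 were measured, and their median log2 fold change was 0.0153, with 5 above 0. With limma 0 of the 10 were called (2 at an unadjusted p under 0.05), and camera gave p = 0.76 with the preset and p = 0.76 with an estimated correlation. Those 2 were KDR (-0.41 ± 0.11, adjusted p = 0.053) and EPO (-0.53 ± 0.18, adjusted p = 0.16), both lower and so against low oxygen, but above the empty spots on 0 of the 4 vegetative arrays in either channel. Members that go both ways with a median near 0 decide neither for nor against low oxygen. A looser rule, written first, had counted these values against low oxygen, and it was replaced after the outcome was seen.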
